A study of Homo sapiens with 12 samples.

How the data were processed

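Polyadenylated RNA of sorted Ramos cells was sequenced as 12 libraries, 6 with miR-28 and 6 with the scrambled vector. The submitters' processing notes name CASAVA 1.8.2, cutadapt, RSEM 1.2.3 and the GRCh38 build. The annotation release, the filter on low genes and the normalization step are not given in the sources used here. The table deposited by the authors holds signal values that are never negative, 1 column per library, with no replicates pooled.

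What these values are was worked out from the numbers. In each library every value was a whole multiple of 1 step, within a tolerance of 0.01 reads for 100% of values, so that whole reads were recovered. TMM factors computed by edgeR from these reads differed from the factors contained in the values by at most 8.9e-16, so that the values are CPM scaled by TMM. Every gene had a value above 1 in at least 1 library, and the lowest maximum was 1.15, so genes expressed below that level were not analysed here. Libraries held 15404730 to 37876636 recovered reads. The value of 3 reads ranged from 0.0830 CPM in the deepest library to 0.181 in the shallowest, and such floors cover counting error only. RSEM gives expected counts, and whether they were rounded before scaling is not stated.

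Gene identifiers were matched to symbols for 12528 of 12725 genes, and positions and 3' UTRs came from GENCODE release 29 on GRCh38, which held 12595 of them. That release may differ from the one the authors used. Reads shared with near-identical copies, such as nuclear copies of mitochondrial genes, and reads of overlapping or antisense genes are uncertain, since the counting is known only as RSEM and no strand setting is given.

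The design fixed before the data were examined had an edgeR quasi-likelihood test for counts and limma for normalized values. As the values are normalized, limma 3.58.1 (trend, robust off) on log2(value + 1) with library batch and group was used for all 12 libraries, in R 4.3.3, with a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on that scale, which understates the change of low genes. No further filter was set on low values; this choice was made after first fits had been seen, and filterByExpr, the filter of the count design, gave a count of 2 genes as well. The design had taken the table for counts. Count tests on the recovered reads with edgeR 4.0.16 and DESeq2 1.42.0 were run as alternatives.

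The labels call the libraries sample pairs. The deviations of both libraries of a pair from their group means correlated across genes by 0.697 to 0.882, and each library correlated best with its own partner, so the pair was taken as a block beside the fit with batch. For 10388 genes with a mean of 5 or more the median SE of the log2 fold change was 0.201 with batch and 0.0944 with the block.

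The genes named were set by a rule: the 10 largest changes in each direction among genes with an adjusted p under 0.05, a mean of 5 or more and the same sign in all 6 pairs; LPP and every measured reported target; up to 4 genes of each other list with the smallest adjusted p, ties by larger fold change; and the 5 smallest adjusted p in each direction, where ties at 1 were broken by the unadjusted p. This gave 114 genes, of which the text gives examples; 1 measured target is not reported here by name. Of 28 gene lists, 25 had at least 3 measured genes and were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry beside it. Seed sites were compared by permutation over genes with 100000 resamples, and with 2000 within 10 classes of 3' UTR length. The summed markers of other cell types were compared by an exact permutation test within batch.

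The fits were tested on simulated data, with counts drawn for the 12725 genes from the pair means and library sizes and 200 genes changed. The limma fit with batch recovered 2% of 100 genes changed by 1.5-fold and 29% of 100 changed by 2-fold, with 0 unchanged genes called. The fit with the block recovered 78% and 97%, with 9 unchanged genes called. The simulated counts had the same dispersion and the same change in every pair. In the data, the SD across genes of the log2 difference within a pair ranged from 0.176 in pair 5 to 0.563 in pair 3. These shares may therefore not carry over to the real fits. Alternatives covered the scaling, the pseudocount, the filter, the test, the terms of the fit and the libraries used. A gene or list that passed in neither fit was taken as having the same call whatever its sign.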

Results

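The effect of microRNA-28 on the transcriptome was measured in Ramos, a human B cell line derived from a Burkitt lymphoma. The cells carried a doxycycline-inducible lentiviral vector, pTRIPZ, with either miR-28 or a scrambled sequence. They were selected with 0.4 µg/ml puromycin, induced for 2 days with 0.5 µg/ml doxycycline and sorted for the red fluorescence of the vector before polyadenylated RNA was sequenced. The 12 libraries form 6 pairs of a miR-28 and a scramble library. Pairs 1, 2 and 3 were prepared in library batch 1 and pairs 4, 5 and 6 in batch 2. The labels give XENO 1 for pairs 1, 4 and 5 and XENO 2 for pairs 2 and 6, and pair 3 has no number. The meaning of XENO is not given. It was taken here to mark 3 transductions, with pair 3 set apart from the numbered ones. Values were given for 12725 genes, as read counts scaled to library size with TMM factors (CPM), and the libraries held 15404730 to 37876636 reads over these genes. Pairs of the same transduction may share cells, so the p-values measure the spread among these samples only.

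The first principal component took 67.6% of the variance and set pairs 3, 4 and 6 apart from pairs 1, 2 and 5. This division is neither the library batch nor the XENO number of the labels. In the scramble library of pair 3, transcripts encoded by the mitochondrial genome took 7.45% of reads, against 3.43% in its miR-28 partner.

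**Figure D1:**
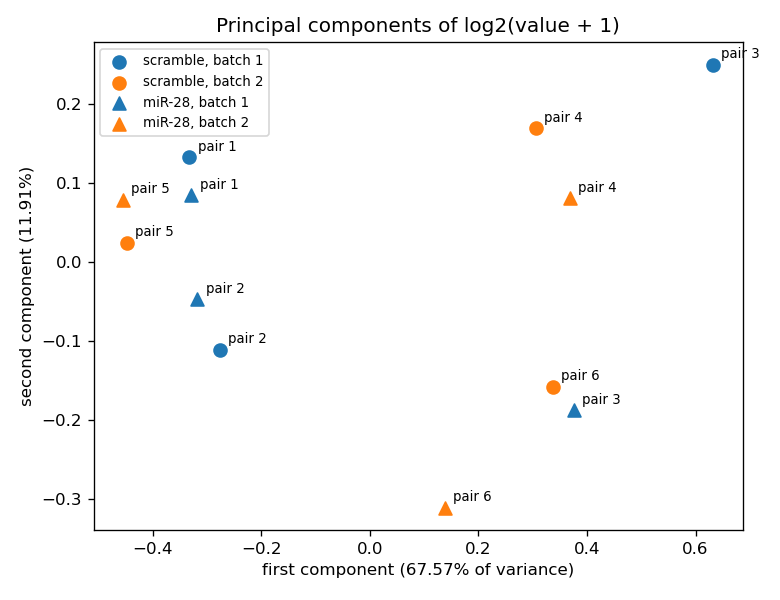
First and second principal components of log2(value + 1) over 12725 genes, with the share of variance on each axis. Circles are scramble and triangles miR-28 libraries, coloured by library batch, and both libraries of pairs 3, 4 and 6 lie at positive values of the first component and those of pairs 1, 2 and 5 at negative values.

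The first comparison asked which transcripts changed when miR-28 was induced. MIR28 was higher in the miR-28 libraries, and SPCS3, a subunit of the signal peptidase complex of the endoplasmic reticulum, was lower. MIR28 (ENSG00000207651, GRCh38 chromosome 3, 188688781 to 188688866, within an intron of LPP) had 0 reads in all 6 scramble libraries and 304 reads in the 6 miR-28 libraries, where its values ranged from 0.983 to 3.16 CPM (mean 1.89 ± 0.856, SD, n = 6). Against a floor of 3 reads over the scramble group as a whole, it was at least 97.6-fold higher, a bound that covers counting error only. Polyadenylated RNA libraries do not measure the mature microRNA, and gene counts do not tell reads of the vector from reads of the genome. SPCS3 (ENSG00000129128, chromosome 4, 176319964 to 176332245) measured 474.0 ± 59.1 CPM in scramble and 256.9 ± 16.5 in miR-28 libraries (SD, n = 6 each). Its log2 fold change was -0.87 with an SE of 0.111, and it was lower in 6 of 6 pairs.

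In limma on log2(value + 1) with batch as a term, these were the 2 genes of 12725 with a Benjamini-Hochberg adjusted p under 0.05, each at 0.0381. At an unadjusted p under 0.05 there were 42 genes, where chance gives 636.2. This fit leaves the differences between pairs in its error, with a median SE of 0.201 against 0.0944 with the pair as a block. Its p-values were therefore conservative, and a lack of calls in it does not show that genes were unchanged. MIR28 is the induced sequence itself, and the call of SPCS3 rested on its presence among the genes tested. With MIR28 left out, SPCS3 had a limma adjusted p of 0.0621 with batch, so that 0 genes passed, with 41 at an unadjusted p under 0.05, and 0.00959 with the pair as a block. With the pair as a block, SPCS3 (adjusted p = 0.00959), MIR28 (0.0239) and NFE2L2 (0.0309) passed in limma, and 929 genes had an unadjusted p under 0.05. NFE2L2 (ENSG00000116044, chromosome 2, 177227595 to 177392697), which encodes the transcription factor NRF2 of the oxidative stress response, measured 129.0 ± 17.2 and 87.6 ± 14.9 CPM (SD, n = 6 each) and had a log2 fold change of -0.56 (limma adjusted p = 1 with batch). The edgeR quasi-likelihood test on the reads recovered from the values, with batch, called 0 genes, with an adjusted p of 0.0623 for both SPCS3 and MIR28 and 45 genes at an unadjusted p under 0.05. DESeq2 with batch called the same number, 2, with 78 at an unadjusted p under 0.05. With the block, NFE2L2 had an adjusted p of 0.0589 in edgeR, 4.89e-09 in DESeq2 and 0.0397 in limma-voom. Limma on reads summed per transduction, with transduction as a block, called 0 genes, so that MIR28 was not called either, with 232 at an unadjusted p under 0.05. Leaving out any 1 of the 6 pairs, or any 1 of the 12 libraries, left 0 calls in the limma fit with batch, with 17 to 104 genes at an unadjusted p under 0.05, while the log2 fold change of SPCS3 without 1 pair stayed between -0.94 and -0.82.

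Further from the threshold, ATPAF1, an assembly factor of the mitochondrial ATP synthase, had a log2 fold change of -0.46 (SE 0.115, lower in 6 of 6 pairs, limma adjusted p = 1, with the block 0.297). AIFM2 (-0.35), low in the miR-28 library of pair 6 in particular, and an antisense gene with no symbol, ENSG00000226849 (-0.56), were the remaining genes among the 5 lowest p-values in that direction, and ARPP21 (0.78), SYNE2 (0.42), MAST1 (0.62) and ARHGAP11A-DT (0.40) followed MIR28 in the other. None of these passed in limma with or without the block. ENSG00000226849 and ARHGAP11A-DT are annotated as antisense, and their reads are uncertain.

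**Figure D2:**
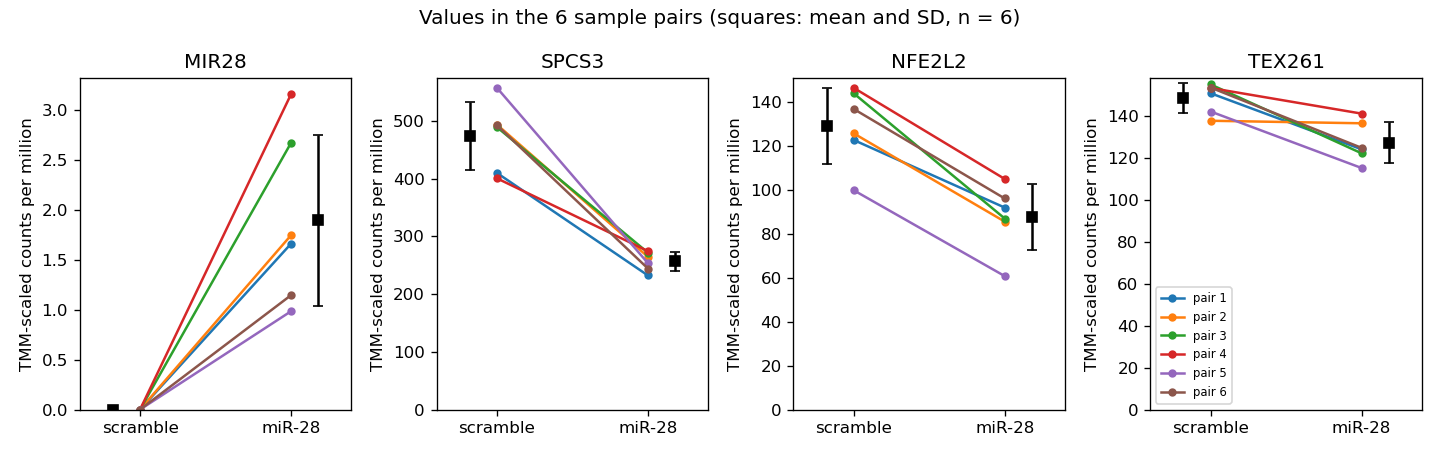
Values of MIR28, SPCS3, NFE2L2 and TEX261 in CPM, with a line joining the scramble and miR-28 libraries of each of the 6 pairs and squares with bars for the group mean and SD (n = 6). MIR28 lies at 0 in every scramble library, and SPCS3 and NFE2L2 lie lower in the miR-28 library of all 6 pairs.

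The second comparison concerned LPP, the host gene of miR-28, and genes named as targets of miR-28 in earlier work. Of the 12 measured of 15 listed targets, 10 had a fold change below 0 and 4 were lower in all 6 pairs, namely NFE2L2, TEX261 (log2 fold change -0.23, SE 0.0899), E2F6 (-0.30, SE 0.129) and N4BP1 (-0.18, SE 0.139). MAD2L1, of the spindle checkpoint (0.16), lay above 0, and HOXB3 (-0.45), RAP1B (-0.14), OTUB1 (-0.08), BAG1 (-0.06), NME1 (-0.06) and RAB23 (-0.05) below. Camera with its preset correlation called the list lower (adjusted p = 0.000289), and the call was lost at an adjusted p = 0.0503 with an estimated correlation. In limma 0 of the 12 passed over all genes and 1, NFE2L2, adjusted over the list alone. With the pair as a block these counts were 1 and 3, the latter adding TEX261 and E2F6. The list's median log2 fold change was -0.12 in batch 1, where camera gave an adjusted p = 0.0505, and -0.19 in batch 2, where it gave 6.73e-05. LPP had a log2 fold change of -0.34 with an SE of 0.411 and was lower in 4 of 6 pairs (limma adjusted p = 1). Whether the study picked any of these targets from these same libraries is not known here.

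The third comparison took the gene lists fixed before the data were examined. All 13 protein-coding transcripts of the mitochondrial genome lay lower in the miR-28 libraries, 12 of them in all 6 pairs, with a median log2 fold change of -0.45. MT-ND1 (-0.61, SE 0.355), MT-ND2 (-0.52, SE 0.232) and MT-ND4 (-0.53, SE 0.399), subunits of respiratory complex I, were among them. The scramble library of pair 3 stood apart in MT-ND4, at 10900 CPM against 2080 to 3840 in the other scramble libraries. Reads of nuclear copies of these genes cannot be told from theirs and make the values uncertain. The list was called by camera (adjusted p = 9.1e-12) but not with an estimated correlation (adjusted p = 0.624). In limma 0 of the 13 passed over all genes or adjusted over the list alone with batch, and 13 passed adjusted over the list alone with the pair as a block. The median difference ranged from -0.17 in pair 4 to -1.18 in pair 3. Without pairs 3 and 6 the list's median was -0.31 (camera adjusted p = 6.19e-10). Nuclear genes of oxidative phosphorylation had a median of 0.0040 (camera adjusted p = 0.874).

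Cell-cycle genes lay higher in the miR-28 libraries, mostly in pairs 3 and 6. Of 54 genes of mitosis 51 had a fold change above 0, with a median of 0.26, and 51 of 52 genes of DNA replication did, with a median of 0.24. Examples were CENPE, a kinetochore motor (0.39, SE 0.18), CDCA2 (0.43, SE 0.444), the thymidine kinase gene TK1 (0.45, SE 0.279), low in the miR-28 library of pair 4, and GINS2 of the replicative helicase (0.50, SE 0.518), none of which passed in limma. Camera called both lists (adjusted p = 9.41e-13 and 9.96e-11), and each had an adjusted p = 0.742 with an estimated correlation. The median difference of the mitosis list was 0.75 in pair 3, whose scramble library had the mitochondrial share of 7.45%, and 0.40 in pair 6, and 0.0041, 0.030, 0.20 and 0.056 in pairs 1, 2, 4 and 5. Without pairs 3 and 6 the median of the DNA replication list was 0.011 and camera no longer called it (adjusted p = 0.493), while the mitosis list had a median of 0.073 and an adjusted p of 0.000156.

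Camera called 5 further lists, none with an estimated correlation. Germinal centre genes (21 of 28 above 0, adjusted p = 0.00452, and adjusted p = 0.742 with an estimated correlation) included POU2F2 (0.34) and ELL3 (0.50). These were the 2 genes of the list that were higher in 6 of 6 pairs. The list's median difference was 0.57 in pair 3 and between -0.018 and 0.096 in the other pairs. Without pair 3 camera did not call it (adjusted p = 0.0869). Ribosomal proteins (56 of 82 above 0, adjusted p = 0.0424; adjusted p = 0.886 with an estimated correlation) included RPS3A (0.26). Proteasome genes (27 of 31 below 0, adjusted p = 0.0025, and adjusted p = 0.833 with an estimated correlation) included PSMB2 (-0.26). The unfolded protein response list (22 of 27 below 0, adjusted p = 0.0471) included EDEM1 (-0.42), and replication histones (14 of 16 below 0, adjusted p = 0.0269) included H2BC21 (-0.35), high in the scramble library of pair 3. Both of these had an adjusted p = 0.742 with an estimated correlation. In single batches, camera called germinal centre genes, ribosomal proteins and replication histones in batch 1 but not in batch 2 (adjusted p = 0.203, 0.51 and 0.0706). It called proteasome genes and the unfolded protein response list in batch 2 but not in batch 1 (adjusted p = 0.433 and 0.873). Without pairs 3 and 6 camera called 4 lists in place of 9, namely the mitochondrially encoded, target and mitosis lists and NF-κB targets (adjusted p = 0.0119). In limma 0 genes of these lists passed over all genes or adjusted over the list alone, and with the pair as a block 1 did adjusted over the list alone, EDEM1. Histone transcripts mostly lack a poly(A) tail, so their level in these libraries depends on the RNA selection. With the pair as a block, 12 lists were called in place of 9, adding MYC targets (adjusted p = 0.022), cholesterol synthesis (0.04) and B cell identity genes of the line (0.04). With the block and an estimated correlation these had an adjusted p = 0.682, 0.682 and 0.662, and 0 lists were called. The other lists were not called by camera with batch. Their adjusted p-values were 0.443 for B cell receptor signalling, 0.34 for NF-κB targets and for the microRNA machinery, 0.161 for plasma cell genes, 0.966 for anti-apoptotic and for pro-apoptotic genes, 0.719 for p53 targets, 0.172 for MYC targets, 0.24 for interferon response, 0.83 for antigen presentation and for glycolysis, 0.12 for cholesterol synthesis, 0.469 for actin and migration, 0.458 for T cell markers and 0.151 for B cell identity. The mean fold change had the other sign than the median for pro-apoptotic genes and p53 targets, and the test the other direction than the median for oxidative phosphorylation.

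**Figure D3:**
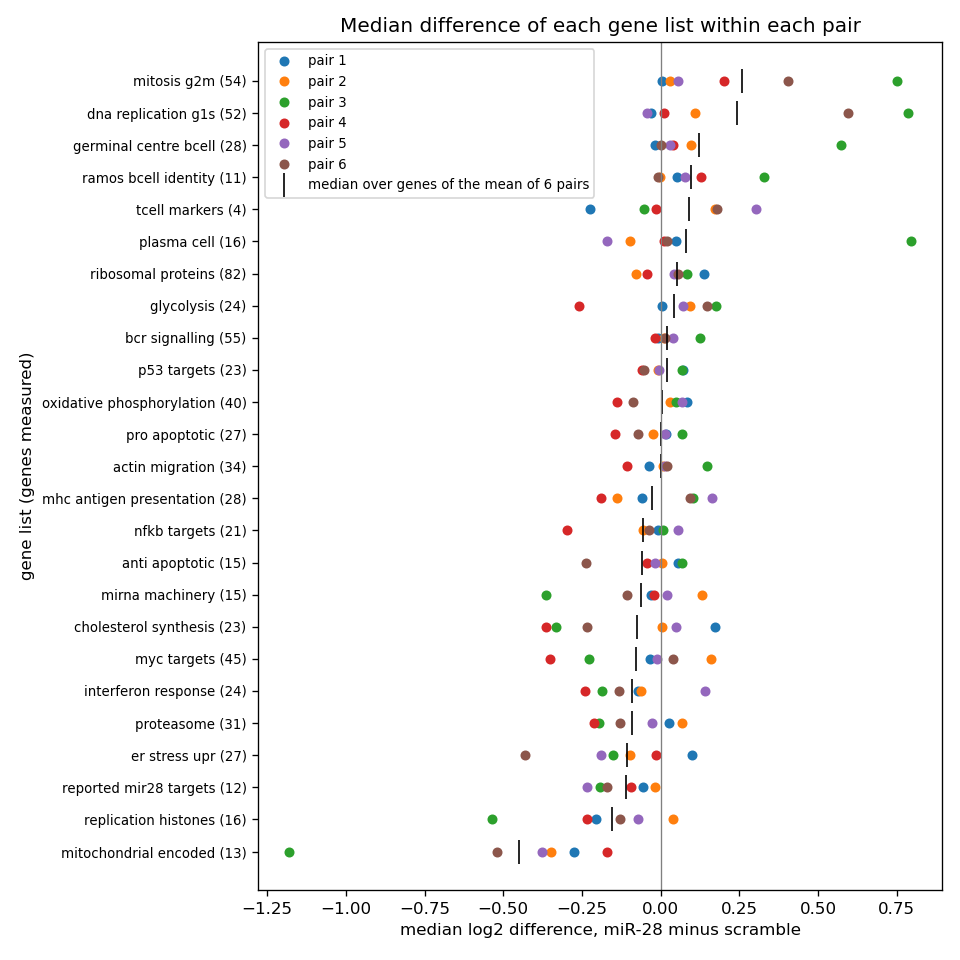
Median log2 difference, miR-28 minus scramble, of the measured genes of each list within each of the 6 pairs (points), and the median over genes of the mean of the 6 pairs (bars); the number of genes measured is in brackets. The mitochondrially encoded list lies below 0 in all 6 pairs, and the mitosis and DNA replication lists reach their highest values in pairs 3 and 6.

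Whether miR-28 acted alike in both library batches was tested as an interaction. In limma 0 genes were called for a different effect by batch, with 9 at an unadjusted p under 0.05 where chance gives 636.2. With the pair as a block limma called 0 as well, with 171 such genes and a smallest adjusted p of 0.697. Both counts lie below that of chance, so these tests were conservative and do not show that miR-28 acted alike. DESeq2 called 1, the readthrough gene PEDS1-UBE2V1 (adjusted p = 0.0439), whose reads overlap those of its neighbours and are uncertain; it was named after its values were seen. Across 10388 genes with a mean of 5 or more, which are not independent replicates, the fold changes of both batches had Pearson's r = 0.476 and Spearman's rho = 0.464, and 65.2% had the same sign. The differences within pair 3 of batch 1 and pair 6 of batch 2 correlated by 0.522. The other combinations of pairs gave -0.155 to 0.196. The agreement of the batches may therefore rest on pairs 3 and 6, and it was not computed without them. SPCS3 had a log2 fold change of -0.85 in batch 1 and -0.90 in batch 2. For the 3 transductions, limma called 0 genes in the F test of the interaction, with 218 at an unadjusted p under 0.05 where chance gives 636.2. DESeq2 called 13, among them BMP6 (adjusted p = 1.15e-07), BLNK (0.00253) and TLR7 (0.033), named after their values were seen. In pair 3, the 1 pair with no XENO number, their log2 differences were 2.40, 1.32 and 1.84, so that this interaction rests on a single pair.

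A direct target of a microRNA is expected to carry its seed site, so fold changes were compared by the 3' UTR. The 1671 genes with a 7mer-m8 site of miR-28-5p (AGCTCCT) in the longest annotated 3' UTR had a median log2 fold change 0.024 below that of 8465 genes with no site of either arm (difference -0.024; two-sided permutation test over genes, p = 1e-05, the smallest that 100000 resamples can give). Genes are not independent replicates, so the p-values of this comparison describe genes within this fit only. When group labels were swapped within pairs, 7 of 32 arrangements gave a difference as large as the real one. Genes with a site had longer 3' UTRs, with a median of 2947 against 1068 bases, and within 10 classes of 3' UTR length the difference was -0.016 (permutation p = 0.001, 2000 resamples). On residuals of a regression on 3' UTR length, GC content and mean expression, it was -0.0096 (permutation p = 0.0406). Of 407 shuffled sites, 25 gave a difference as low as the real site, and 34 did within the classes of length. The difference lay below 0 in 4 of 6 pairs, at -0.11 in pair 3 and between -0.026 and 0.022 in the others. The 856 genes with a site of miR-28-3p differed by -0.013 (permutation p = 0.0391), and by -0.0029 within the classes of length (permutation p = 0.621). SPCS3 had 0 such sites of miR-28-5p and 1 7mer-A1 site in its 3' UTR of 3915 bases. NFE2L2 had 0 of miR-28-5p and 1 of miR-28-3p, and TEX261, E2F6 and ATPAF1 had 1 of miR-28-5p each. Among the other reported targets named above, BAG1 had 3 of miR-28-5p, HOXB3 and N4BP1 2 each, RAP1B, OTUB1, RAB23 and MAD2L1 1 each, and NME1 0. Targets that barely changed or rose, such as BAG1 (-0.06) and MAD2L1 (0.16), thus carried sites too.

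Of the T cell list 4 genes were measured, ZAP70, IL7R, CD28 and TRBC2, which summed to 67.1 ± 32.2 CPM in scramble and 82.7 ± 33.0 in miR-28 libraries (SD, n = 6 each; exact permutation test within batch over 400 arrangements, two-sided p = 0.42). Within pairs the sum was higher in the miR-28 library in 6 of 6 pairs (exact permutation by sign flips within pairs, two-sided p = 0.0312, the smallest that 6 pairs allow). Without TRBC2, left out after the values were seen, the other 3 genes summed higher in 3 of 6 pairs (exact p = 0.781). Most of the sum was TRBC2, with a mean of 67.2 over the 12 libraries and 8.69 in the scramble library of pair 3. PECAM1, the measured gene of the stroma list, gave 1.59 ± 0.581 and 1.53 ± 0.504 (exact permutation p = 0.84; within pairs 0.75). For the myeloid and epithelial lists 0 genes were measured.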

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

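The tests of the pairs that stand apart, of the difference shared by pairs 3 and 6 and of the mitochondrially encoded transcripts were chosen after those patterns were seen. Among the 6 libraries of a group, 1 library was set against the rest by Dixon's ratio at its 95% limit. This marked 16 of 236 groups tested, where chance marks about 1 in 20.

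Of these, 8 concern the scramble library of pair 3. Its share of mitochondrially encoded reads was 7.45% (the other scramble libraries 1.54 to 2.88%), its 10 highest genes took 7.93% of reads (3.77 to 4.75%) and 29 genes were at 0 (10 to 17). In CPM it had MT-ND4 at 10900 (2080 to 3840), BLNK at 36.6 (89.9 to 131), H2BC21 at 6.06 (0.907 to 1.70), SYK at 166 (323 to 432) and TRBC2 at 8.69 (42.8 to 83.8). The miR-28 library of pair 4 had RPL12 at 395 (823 to 987), RPS3A at 1080 (1690 to 2020), SDHC at 129 (82.2 to 96.3) and TK1 at 58.3 (86.3 to 105). The miR-28 library of pair 6 had AIFM2 at 6.18 (7.93 to 9.18) and MSMO1 at 45.6 (95.4 to 117), that of pair 3 had IL7R at 0.597 (2.57 to 3.97), and the scramble library of pair 6 had DDB2 at 16.4 (6.07 to 8.77).

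Pairs 3, 4 and 6 stood apart from pairs 1, 2 and 5 on the first component. The labelled library batch is argued against by 4 libraries on the other side from the rest of their batch, and the transduction by 2 transductions with libraries on both sides. GC content and transcript length took 4.48% of the variance of the gene loadings. The TMM factors ranged from 1.01 to 1.08 in the libraries of pairs 3, 4 and 6. In those of pairs 1, 2 and 5 they ranged from 0.912 to 0.967, a difference that was not tested as an explanation. Other differences between the pairs stay open, and no biological explanation was tested.

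The differences within pairs 3 and 6 correlated across genes by 0.522, against -0.155 to 0.196 for the other combinations of pairs. A candidate explanation is that they follow the state that separates the pairs. Their correlations with the first component of the scramble libraries of the other 5 pairs were 0.336 for pair 3 and 0.564 for pair 6. These are sizes without a sign, and none were computed for pairs 1, 2, 4 and 5. The component used for each of pairs 3 and 6 includes the scramble library of the other. The sizes are therefore not independent of the correlation of 0.522. A higher level of miR-28 stays open, since these libraries do not measure the mature microRNA. MIR28 was at 2.67 CPM in pair 3 and 1.14 in pair 6, on either side of the median of 1.70. It was highest in pair 4, at 3.16. By the bound first set, a value below the median in pair 3 or 6, the explanation would be argued against. That bound was replaced after the value of pair 6 had been seen. An effect of miR-28 that depends on that state stays open too, as untested.

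The lower level of mitochondrially encoded transcripts did not rest on pair 3, without which the list's median log2 fold change was -0.34. Nor did it come from the scaling, since the highest median under RLE, upper quartile and plain library size was -0.44. RNA quality and handling of the cells were not tested, and an effect of the miR-28 vector stays open, as untested.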

How the results depend on the processing

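No result that passed its test changed direction under any alternative run. Several alternatives were chosen after seeing the data. In the gene tests these were edgeR other than with batch, limma-voom other than with batch, and both tests below that gave 21 genes. Also added were the tests with the division of pairs seen in the data and the blocked leave-one-out fits. So were the fits with MIR28 left out of the genes tested and those without pairs 3 and 6. The marker test within pairs and all alternatives for LPP and the reported targets were chosen then too. In the list and seed comparisons these were the blocked list tests with an estimated correlation or fry, the residuals, and 7mer-A1 and 6mer sites. The edgeR test with batch and filterByExpr were the design's choices for counts, run here beside limma once the values proved normalized. Stratifying the seed comparison by 3' UTR length was in the design too, without a number of classes. The count of 2 genes became 0 with library size alone, upper quartile factors, the stricter filter (5 CPM in 6 libraries), a pseudocount of 5, a fold minimum of 1.2, reads summed per transduction, batch 1 or batch 2 alone, the edgeR test with batch, with MIR28 left out of the genes tested, without pairs 3 and 6, and without any 1 replicate (0 to 0), with 5 to 232 genes at an unadjusted p under 0.05 in these limma fits and 45 in edgeR. SPCS3 then had limma adjusted p-values of 0.0523 under the stricter filter, which removes MIR28, 0.0585 with a pseudocount of 5, and 1 in each batch alone. Its unadjusted limma p was 4.88e-06 in the main fit, 5.07e-06 under that filter, 4.6e-06 with that pseudocount and 7.89e-06 with upper quartile factors. With a pseudocount of 5 that of MIR28 went from 5.99e-06 to 9.45e-05, so the call of SPCS3 lost the gene it rested on. Fewer libraries or genes are part of the construction of some settings, and for the remaining ones the cause was not tested. With the pair as a replicate block edgeR called 1 gene, DESeq2 and limma-voom with quality weights 21 each (4 up and 17 down), and limma without pairs 3 and 6 called 4, the added gene being ENSG00000272410; the cause was not tested. The 3 genes of the limma fit with the replicate block became 0 to 3 without 1 pair, with 0 without pair 1, 2 or 6 and 1 without pair 4. Among the named genes the count of 2 became 0 with library size alone, in each batch alone, without pairs 3 and 6 and without any 1 replicate, and among LPP and the reported targets 0 became 1 with the replicate block, which changed no other call of a named gene. The 9 called lists became 0 with an estimated correlation and with fry, 4 without pairs 3 and 6, and with the replicate block 0 with an estimated correlation and 1 with fry. The batch interaction rose from 0 to 1 gene and the transduction interaction from 0 to 13 in DESeq2; the cause was not tested. The miR-28-3p difference was -0.0135 for 8mer sites, -0.00288 within length classes and -0.0104 in both sets of residuals, no longer past the threshold, and that of miR-28-5p went from -0.024 to -0.00958 and -0.00922 in residuals (permutation p = 0.0406 and 0.0464). The sum of T cell markers had an exact p of 0.0312 with the replicate block, by sign flips within pairs, in place of 0.42; the cause was not tested. With the pair as a block the median SE was 0.0944 in place of 0.201 at the same depth, and the calls went from 2 to 3; depth itself was not varied.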

Other observations

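The comparisons of splits that keep MIR28 and the test of shuffled sites on genes lower in all 6 pairs were planned before their results were seen. The splits without MIR28 and the odds ratio of the real site were chosen after. Of 100 splits of the libraries within batches, drawn at random with the real one included, 4 gave as many as 2 genes, a share under 0.05, and the highest other gave 4656. That split and another with 3129 parted 2 pairs, where the real one parts 6, and kept most libraries of pairs 3, 4 and 6 on 1 side, which points to a structure of the samples. Of the 32 splits that part every pair, 1, the real one, gave as many genes with batch and 1 with the block, and the highest other gave 0 in both. The real split was bound to call MIR28, the induced sequence. Without it the real split gave 0 genes with batch, as did all 32, so chance is not excluded for the genes called with batch. With the block it gave 2, SPCS3 and NFE2L2, and was the 1 split of 32 to give as many (highest other 0). That is the smallest share 32 splits allow, and the splits take pairs of the same transduction as independent. Chance is therefore argued against for that count only if the pairs are independent. Reads summed per transduction, with transduction as a block, gave 0 genes in limma. That fit has a single sum per group and transduction, and pair 3 alone makes up a transduction. It did not call MIR28 either, so its 0 cannot decide whether SPCS3 and NFE2L2 changed. For the gene lists chance is not excluded: 56 of 100 splits within batches gave as many as 9 called lists, with up to 14, and 8 of the 32 that part every pair, with up to 11. With 0 genes in either interaction, all 10 divisions of the pairs gave as many by batch (highest other 0), too few divisions for a share under 0.05. All 60 assignments to transductions gave as many, with up to 3. Both were bound to, since no count lies below 0, so these splits decide nothing.

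A hypothesis was that genes lower in all 6 pairs may include direct targets of miR-28-5p. Of 12725 genes 279 were lower and 263 higher in all 6 pairs, where chance gives 198.8 each if the pairs are independent. The differences within pairs 3 and 6 correlated by 0.522, so that number may be too low and no excess is shown. Among those with an annotated 3' UTR, 59 of 227 lower genes (26.0%) and 39 of 240 higher genes (16.2%) had a 7mer-m8 site, an odds ratio of 1.81 (95% interval 1.12 to 2.93, Fisher's exact p = 0.0122, genes not being independent). However, 13.0% of 407 shuffled sites gave an odds ratio as high, so 3' UTR length and base composition could give it and the hypothesis stays open.

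Of the 32 splits that part every pair, 7 gave a difference between genes with and without a miR-28-5p site as large as the real one, and 17 did for miR-28-3p. In a search over all 7-mers made after the seed comparison was seen, on residuals of the fold change, the 7mer-A1 site of miR-28-5p ranked 19 of 16119 by lower values and its 7mer-m8 site 982. The 7mer-m8 site of miR-28-3p ranked 332.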
